A study of Homo sapiens with 3 samples.

How the data were processed

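RNA levels were measured in DLD1, a human colon cancer cell line, with 3 biotin-labelled Affymetrix whole-transcript arrays, 1 for each of 3 conditions: a control siRNA, siH19-1 and siH19-2, the 2 siRNAs against H19. H19 is an imprinted long noncoding RNA that hosts the microRNA gene MIR675. Per the labels' protocols, siRNA was used at 50 nM and each array was made from 500 ng of total RNA. The protocol gives 48 hours of transfection and the series' design text gives 24 hours, and which of these is right is not settled here. Per the submitters' processing notes, values were made with Affymetrix Expression Console and RMA, a method that corrects background, normalizes between arrays and summarises probes. Their versions are not given in the sources used here.

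The deposited values are on a log2 scale, from 1.78 to 19.93. Of the probe sets, 315 (control), 319 (siH19-1) and 337 (siH19-2) lay above 16, the log2 ceiling of a 16-bit scanner, and 30, 36 and 36 held the top value of 19.93. A transformation beyond plain RMA is therefore possible and not stated, so a fold given below is a fold on the deposited scale. Detection calls and background signals were not used here, so a dim probe set cannot be called present or absent. The number of arrays limits the precision of every value.

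The platform's annotation, which can be old, gave 1 gene symbol to 23781 of 67528 probe sets, several symbols to 1543 and none to 42204. The symbols covered 22465 genes. A RefSeq gene table of assembly GRCh38.p14 listed 22167 of them and changed 0 symbols; it was used for names and kinds of gene, and no coordinates were taken from it. For the 479 genes with several probe sets the one with the highest mean over the 3 arrays was taken. Genes with a mean log2 signal of at least 5 were compared (9630 genes), which left out 12835. Among 70 compared genes with another probe set past the minimum, the difference from control varied between probe sets with an SD of 0.224 for siH19-1 and 0.294 for siH19-2. A probe set shared by several genes was given no single gene's name, except that the H19 probe set, shared with MIR675, was read as the targeted transcript.

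With 1 array per condition a difference has no replicate check, and no p-value was computed from single differences. A gene was said to rise, fall or change when its deposited signal differed at least 1.5-fold. Genes changed in the same direction with both siRNAs were set beside 100 simulations of unchanged arrays that share 1 control array, in which the whole difference between the siRNA arrays was taken as noise, and beside the overlap of independent lists. A linear model (limma 3.58.1 in R 4.3.3) with both siRNA arrays against the 1 control array was an alternative, with 1 residual degree of freedom and the lone control assumed to vary like the siRNA arrays. Other values were computed with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and figures were drawn with matplotlib 3.10.9. On simulated data of 9630 genes for the comparison of both siRNAs with control, the rule of size in both found 88.0% of 100 genes changed 2-fold, 100.0% of 100 genes changed 4-fold and 2.99% of 9430 unchanged genes, and limma found 0.0% of each.

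Before the data were examined, 25 gene lists were fixed: imprinted genes with the H19 locus, RB and E2F regulators, E2F targets of G1/S, G2/M genes, the Mediator kinase module with the beta-catenin core, WNT targets, p53 targets, interferon response, integrated stress and unfolded protein response, cholesterol synthesis, epithelial adhesion and keratins, mesenchymal and fibroblast markers, leukocyte and endothelial markers, intestinal differentiation, let-7 targets, reported miR-675 targets, hypoxia and glycolysis, RNA interference machinery, TGF-beta and YAP targets, growth factor immediate early genes with ERK feedback, NF-kB and chemokines, replication-dependent histones, ribosomal proteins, oxidative phosphorylation, and apoptosis regulators. The RB, E2F, Mediator and beta-catenin lists were chosen knowing which pathways the study followed, so they are not independent evidence. After the data were seen, 3 lists were added: ribosome biogenesis, mitochondrial ribosomal proteins, and aminoacyl-tRNA synthetases. A list's median difference was ranked among 10000 random lists of the same size matched on mean expression in 20 bins. A list with at least 5 compared genes was said to stand apart where its percentile lay below 2.5, or above 97.5, with both siRNAs. The percentiles describe these arrays and were not corrected for the 23 lists ranked. In simulated data, 30 genes lowered 2-fold ranked at percentile 0.0 with both siRNAs, and 30 unchanged genes at 65.9 and 85.1.

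The rule for named genes was also fixed beforehand. It took H19, MIR675, RB1, E2F1, CDK8, CTNNB1, CCNC and CDK19; the 12 genes highest and the 12 lowest with both siRNAs by the smaller of the 2 differences; the 5 highest and the 5 lowest in siH19-1 against siH19-2; and the 4 members of each list with the largest mean difference in size. Other genes named were chosen after their values were seen, as the text says.

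The alternatives fixed beforehand were no signal minimum or a minimum of 7, median centring, quantile normalization, cyclic loess, the mean of all probe sets of a gene, every probe set on its own, thresholds of 2-fold and 1.3-fold, limma, the mean of the 2 differences, the mean in place of the median of a list, and random lists not matched on expression. Chosen after seeing the data were protein-coding genes alone, genes below a log2 signal of 14, the removal of probe sets of alternative haplotypes or unplaced contigs (67 genes), and gene lists after median centring or quantile normalization. Off-target matches of the siRNAs were not analysed here.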

Results

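Gene expression was profiled in DLD1 colon cancer cells treated with a control siRNA or with either of 2 siRNAs against the long noncoding RNA H19, with 1 array for each of the 3 conditions. The design asks how expression changes when H19 is depleted, and a pair of siRNAs allows changes found with both to be told from changes found with 1. Median log2 signals over all probe sets were 3.47 with control siRNA, 3.53 with siH19-1 and 3.57 with siH19-2. Between arrays, Pearson correlations across the 9630 compared genes, which are not independent replicates, were 0.993 (control and siH19-1), 0.985 (control and siH19-2) and 0.988 (siH19-1 and siH19-2). There were no replicates, so differences below are between single arrays and carry no error. Mesenchymal and fibroblast markers had 0 of 23 measured genes past the signal minimum, with FN1, which encodes fibronectin, the brightest at a mean log2 signal of 4.64. Among leukocyte and endothelial markers 1 of 21 passed, the macrophage gene CD68, at 5.95, 5.85 and 5.98 in control, siH19-1 and siH19-2.

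The probe set of the targeted transcript read lower with both siRNAs, by less than 1.5-fold. The probe set annotated to both H19 and MIR675 (TC11001273.hg.1) had a log2 signal of 7.88 with control siRNA, 7.74 with siH19-1 and 7.37 with siH19-2. These values are differences of -0.14 and -0.51, or 90.8% and 70.2% of the control signal. Among 2988 probe sets within 0.5 log2 units of its signal, the differences ranked at percentiles 31.1 and 10.8. Their SDs were 0.309 and 0.437, and 3230 and 1087 of the 9630 compared genes were lower by more. After quantile normalization or cyclic loess the siH19-1 difference was -0.06. The signal goes in the direction of the labels, but with siH19-1 it lay well inside the spread of probe sets of like signal. With siH19-2, at -0.51 against an SD of 0.437, it was not outside that spread either. Neither difference by itself shows depletion.

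With siH19-1, 152 genes rose and 253 fell. The deepest decreases included OLR1, which encodes a scavenger receptor for oxidised LDL (log2 15.86 to 12.34, -3.52), the small nucleolar RNA SNORA14A (-3.05), SNX6, a sorting nexin of endosome-to-Golgi transport (-2.72), and SS18, a subunit of the BAF chromatin remodelling complex (-2.53). TULP3, an adaptor for transport into cilia, rose by 2.76 and the small nucleolar RNA SNORA2A by 2.56. Differences with siH19-1 were more spread for the 129 small nucleolar RNAs compared (SD 0.59) than for protein-coding genes (SD 0.27). Cholesterol synthesis genes were lower as a group: the median of 20 genes was -0.44, and 0 of 10000 random lists were as low. NSDHL (-0.76) and SC5D (-0.62), enzymes of the late sterol pathway, fell, as did MSMO1 (-0.76), named after its values were seen. After quantile normalization SC5D was at -0.55, under 1.5-fold. LSS, the lanosterol synthase, was at -0.37, and 0 of the 20 rose. With siH19-2, NSDHL (-0.50), SC5D (-0.40) and LSS (-0.40) were below control as well, whereas MSMO1 rose (0.63). Of the 20 genes, 9 were below control with both siRNAs, a share near the 45.6% of all compared genes.

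Of the groups that lay higher than random lists with siH19-1, the interferon response kept this place with no signal minimum and with a minimum of 7. Interferon response genes had a median of 0.11 (percentile 99.7, 15 genes), with IFI6 at 0.46 and RIGI, the cytosolic RNA sensor, at 0.32, and 0 of them rose or fell. Apoptosis regulators had a median of 0.05 (percentile 98.4, 20 genes); the BH3-only gene PMAIP1 (1.02) and CYCS, cytochrome c (1.21), rose. Integrated stress and unfolded protein response genes had a median of 0.05 (percentile 98.9, 27 genes), with the cystine transporter SLC7A11 up by 0.76 and the chaperone gene HYOU1 at -0.56. With a signal minimum of 7 the last 2 groups lay inside the range of random lists (percentiles 94.8 for apoptosis and 96.2 for stress), as did apoptosis with no minimum (92.0). After cyclic loess the siH19-1 medians were 0.17 (interferon), 0.12 (apoptosis) and 0.12 (stress). Of the genes changed with siH19-1, 37.5% were higher, against 53% after quantile normalization and 52.5% after cyclic loess, so the balance of directions rested on the scaling. Of all compared genes, 4.21% changed, and a stricter threshold of 2-fold left 78 genes.

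With siH19-2, 283 genes rose and 862 fell, 2.83 times as many in all as with siH19-1. IDH3A, a catalytic subunit of mitochondrial isocitrate dehydrogenase, dropped by 4.15 (log2 12.70 to 8.55), and MYBL2, a transcription factor of proliferating cells, dropped by 3.58. SLC2A1, the main basal glucose transporter, dropped by 2.93, and the desmosomal cadherin DSG2 by 2.66. The long noncoding RNA AFAP1-AS1 (-2.64), C11orf24 (-2.73) and IGFL4 (-2.34) fell as well. CDK8 (TC13000068.hg.1), the kinase of the Mediator complex, went from 9.57 to 7.25, a difference of -2.32, against -0.55 with siH19-1, which is under 1.5-fold.

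Several signalling groups were lower with siH19-2. Growth factor immediate early and ERK feedback genes had a median of -0.41 (20 genes, 0 of 10000 random lists as low), with 5 lower (8 after median centring), among them EGR1 (-1.57), CCND1 (-1.24), MYC (-1.08) and the receptor EPHA2 (-0.59). NF-kB and chemokine genes had a median of -0.42 (percentile 0.23, 13 genes): CXCL1 (-1.16), CXCL8 (-1.07) and CXCL2 (-0.78), which attract neutrophils, fell, and the cytokine gene IL18 rose by 1.28. Replication-dependent histones had a median of -0.46 (percentile 0.01), and 8 of 17 fell (4 after quantile normalization), including H2AC13 (-0.91), H1-3 (-0.84), H1-4 (-0.79) and H2BC11 (-0.65). TGF-beta and YAP targets had a median of -0.29 (percentile 1.04, 14 genes); the inhibitors of differentiation ID1 (-2.43) and ID2 (-1.21), TNFRSF12A (-1.41) and TGFB2 (-1.07) fell. The let-7 targets had a median of -0.30 (percentile 1.71, 15 genes), with IGF1R at -0.62 and RRM2 at -0.63. Of its 5 genes that fell, CDC25A and RRM2 are also on the G1/S list and MYC on the ERK feedback list, so these groups are not separate. Among 7 imprinted genes (median -0.37, percentile 2.08), PHLDA2 fell (-1.26), PLAGL1 was at 0.13 (0.80 with siH19-1, where it rose), and ASCL2 (-0.53) and IGF2R (-0.39) did not reach 1.5-fold, though ASCL2 did after median centring (-0.61). After quantile normalization EPHA2 (-0.49), H2BC11 (-0.47) and RRM2 (-0.42) were under 1.5-fold.

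With siH19-1 these 6 groups had medians from -0.14 (histones) to -0.03 (NF-kB), inside the range of random lists. Some of their genes fell with siH19-1 as well: EGR1 (-0.91), CCND1 (-0.71), ID1 (-0.77) and the let-7 target CDC25A (-1.05). TNFRSF12A (-0.58) was just under 1.5-fold, and H2AC13 (-0.42), H1-3 (-0.42), H1-4 (-0.46) and H2BC11 (-0.44) were lower by less. MYC (0.03), CXCL1 (-0.06) and CXCL8 (0.08) did not follow. The siH19-2 place of 3 of the 6 groups depended on the genes or scaling used. TGF-beta and YAP targets ranked at percentile 12.7 with no signal minimum (median -0.03) and 6.63 with a minimum of 7. The let-7 targets ranked at 8.06 with a minimum of 7 and 3.66 after quantile normalization, chosen after seeing the data, and the imprinted genes at 5.67 with no minimum (median 0.00) and 3.02 after quantile normalization. The siH19-2 medians after quantile normalization were -0.27 (NF-kB), -0.19 (TGF-beta and YAP), -0.15 (let-7) and -0.24 (imprinted genes). With no signal minimum the histones stood apart with both siRNAs (-0.14 and -0.38). The groups that lay higher with siH19-1 had siH19-2 medians inside the range of random lists: interferon response 0.02 (percentile 83.4), apoptosis regulators 0.06 (percentile 95.9) and the stress response -0.19 (percentile 3.45). Between the siRNAs themselves the interferon response (percentile 95.9) and apoptosis regulators (71.9) lay inside that range too, so these 2 groups were not set apart by siRNA. IFIT5, an interferon-induced RNA-binding protein (-1.21), and the death receptor pathway genes TNFRSF10A (-1.17) and FADD (-0.63, or -0.56 after quantile normalization) fell with siH19-2, while OAS3 was at -0.54. In the same groups PMAIP1 rose with siH19-2 as well (0.80). CYCS (0.57) and RIGI (0.50) were under 1.5-fold with siH19-2 but reached it after quantile normalization (0.70 and 0.59).

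Of the genes changed with siH19-2, 24.7% were higher, against 14.8% after median centring, 45.5% after quantile normalization and 38.6% after cyclic loess. Of all compared genes, 11.9% changed, and 302 did at 2-fold.

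With each siRNA against the same control array, 171 genes changed in the same direction, 66 higher and 105 lower. A deviation of that 1 control array cannot be told from an effect of the siRNAs here. CDH1 (TC16000559.hg.1), which encodes E-cadherin, the adhesion protein of epithelial junctions, rose by 1.83 with siH19-1 and 1.96 with siH19-2, from a log2 signal of 10.27 to 12.10 and 12.23. TULP3 (TC12003230.hg.1) rose by 2.76 and 2.15, LRRC58 by 1.71 and 1.67, and DCP2, the mRNA decapping enzyme, by 1.73 and 1.60. SNORA2A (2.56 and 1.55), ENPP5 (1.32 and 1.80), SPRING1, a regulator of SREBP signalling (1.22 and 1.31), and SH3BGRL2 (1.16 and 1.20) followed. The lysosomal tethering gene VPS33A (1.36 and 1.08), POMK, a kinase that modifies dystroglycan glycans (1.08 and 1.05), RO60, which binds Y RNAs (1.03 and 1.3), and the kinetochore gene CENPQ (1.03 and 1.19) completed the 12 highest.

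The microRNA gene MIR2054 fell most with both (-3.27 and -2.07), followed by NETO2, an auxiliary subunit of kainate receptors (-1.59 and -1.13). CDC25A, the phosphatase that activates cyclin-dependent kinases, fell by 1.05 and 1.24. The planar polarity and WNT receptor genes VANGL1 (-0.95 and -1.12) and FZD6 (-1.03 and -1.17) fell, as did CEMIP, a hyaluronan-binding protein (-0.95 and -1.98), the BMP modulator TWSG1 (-1.48 and -0.99) and the cytochrome P450 gene CYP1B1 (-1.08 and -1.15). ELOA, the elongin A subunit (-1.03 and -1.39), FARSA, a phenylalanyl-tRNA synthetase subunit (-0.94 and -1.03), and the ribosome biogenesis genes MAK16 (-1.0 and -1.22) and WDR43 (-0.97 and -1.0) were also among the 12 lowest.

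**Figure D1:**
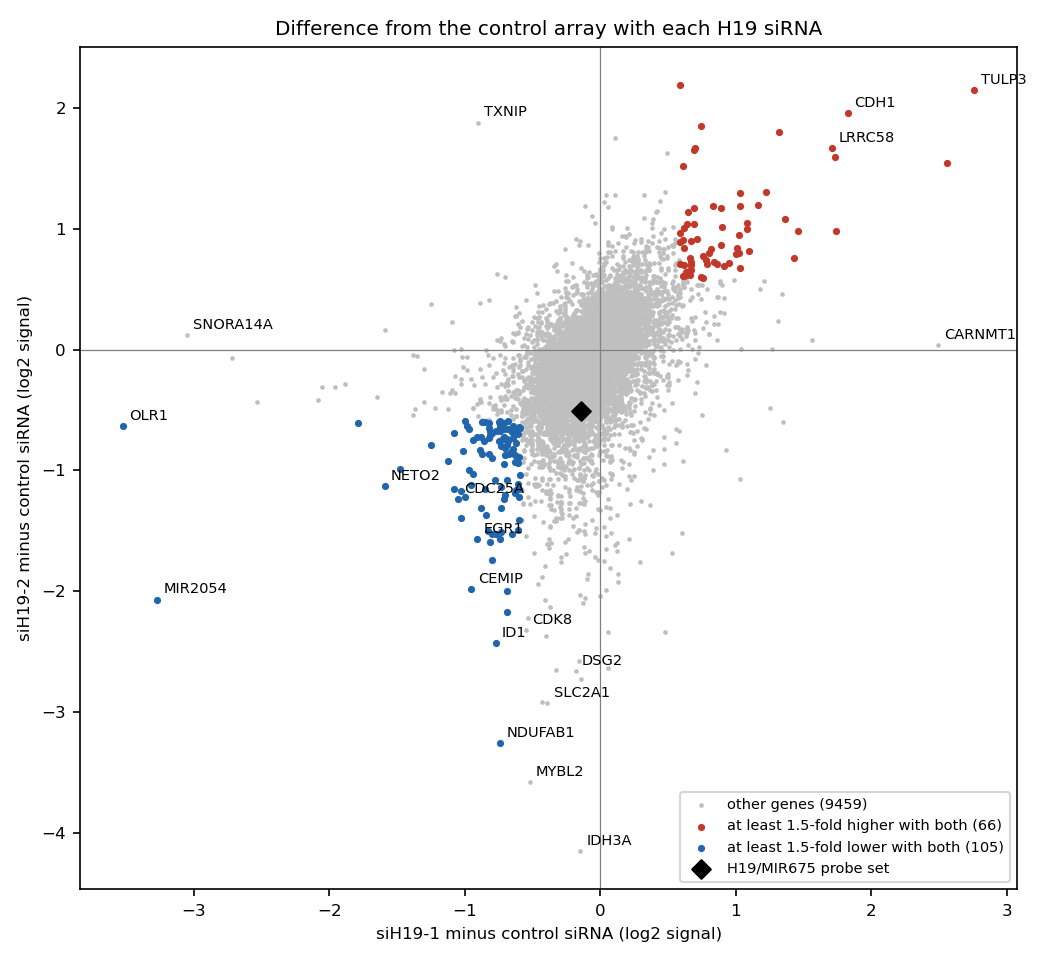
Each point is 1 of 9630 genes, with its log2 difference from the control array for siH19-1 on the horizontal axis and for siH19-2 on the vertical axis; the 66 genes at least 1.5-fold higher with both are red and the 105 lower with both are blue. The H19/MIR675 probe set (black) lies at -0.14 and -0.51. IDH3A and MYBL2 lie far down the vertical axis (-4.15 and -3.58), with IDH3A at -0.15 and MYBL2 at -0.52 on the horizontal one.

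The number of genes changed with both was below what the shared control array gives by itself in the simulation. Unchanged arrays that share 1 control gave 295 genes on average over 100 simulations (range 237 to 357), 148.0 higher and 147.0 lower. Taking the whole siRNA-to-siRNA difference as noise makes this an upper estimate if the control array was no noisier. Independent lists of the same sizes would share 4.47 higher and 22.6 lower genes. The differences of both siRNAs had the same sign for 69.2% of genes, with a Pearson correlation of 0.477 across genes against 0.50 simulated, and a covariance of 0.0536 against 0.0669. The Spearman correlation, 0.524, lay above the simulated mean of 0.47 and above the highest of the simulations, 0.49. By rank the agreement thus exceeded what the simulation gave. The simulated arrays had equal noise, whereas the estimated variances of single arrays were 0.0536 (control), 0.0243 (siH19-1) and 0.1085 (siH19-2). Each estimate is the covariance of the 2 differences that share the array, and assumes that the other arrays share no effect. A change common to both siRNAs would thus be counted as variance of the control array. The simulation also held no shift shared by kind of gene, so the excess cannot be read as an effect of H19. The covariance, observed minus simulated, was -0.0133, and the 1 control array cannot be split. Of the 171 genes, 38.6% were higher, against 26.5% after median centring, 65.6% after quantile normalization and 60.8% after cyclic loess. With limma, 0 genes had an adjusted p under 0.05 (lowest adjusted p 0.863), and 354 had an unadjusted p under 0.05, where 481.5 of 9630 would by chance.

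Of the 23 lists with at least 5 compared genes, 3 stood apart with both siRNAs, all lower, and all of the cell cycle. E2F targets of G1/S, which encode the machinery of DNA replication, had medians of -0.24 with siH19-1 and -0.42 with siH19-2; 2 and 0 of 10000 random lists were as low. Of their 43 genes, 36 were below control with both siRNAs, 8 fell with siH19-1 and 18 with siH19-2, and the same 8 fell with both. Of all compared genes, 45.6% were below control with both, 2.6% fell with siH19-1 and 9.0% with siH19-2. After cyclic loess 5 fell with siH19-1, the same 5 with both, and after quantile normalization 6 and 5 did. The 8 included DSCC1, a subunit of the CTF18 clamp loader (-0.80 and -1.53), GINS2 of the replicative helicase (-0.88 and -1.31) and CDC25A. MCM3, a helicase subunit, fell with siH19-2 (-2.06) and was at -0.11 with siH19-1. The siH19-2 median was -0.24 after quantile normalization, chosen after seeing the data, and the list still stood apart. It was fixed knowing the pathways the study followed, so it is not independent evidence.

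RB and E2F regulators had medians of -0.23 and -0.48 over 21 genes, with 54 and 0 of 10000 random lists as low. Of these, 2 fell with siH19-1 and 7 with siH19-2. The 2 that fell with both were CCND1, cyclin D1 (-0.71 and -1.24), and CCNE2, cyclin E2 (-0.71 and -0.95). After quantile normalization CCND1 was at -0.58 with siH19-1, which left CCNE2. CCNE1 (-0.55 and -1.54) and the repressor E2F7 (-0.36 and -1.60) fell with siH19-2. RB1 (TC13000190.hg.1), the retinoblastoma gene, was at 0.10 and -0.48, and E2F1 at -0.23 and -0.27. Like the G1/S list, with which it shares 3 genes, this list was fixed knowing the pathways the study followed, so it is not independent evidence. Its siH19-2 median was -0.28 after quantile normalization and -0.27 with no signal minimum, and it stood apart under both.

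G2/M genes, which drive mitosis, had medians of -0.17 and -0.31 over 47 genes (86 and 7 of 10000 random lists as low). Of them, 32 were below control with both siRNAs (45.6% of all genes were), while 2 fell with siH19-1 and 6 with siH19-2 (10 after median centring). The mitotic cyclin CCNB1 (-0.63 and -0.93) fell with both; BIRC5, survivin (-0.88 and -0.43), fell with siH19-1; CCNA2, cyclin A2 (-0.31 and -0.79), and the microtubule-associated GTSE1 (-0.39 and -0.70) fell with siH19-2. With the mean in place of the median, the siH19-1 value was -0.15 at percentile 4.96, and the list no longer stood apart. The medians were -0.09 and -0.19 after cyclic loess, and -0.09 and -0.15 after quantile normalization. CCNB1 with siH19-1 was at -0.56 and -0.54 after these, and 0 genes of the list fell with both under either.

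**Figure D2:**
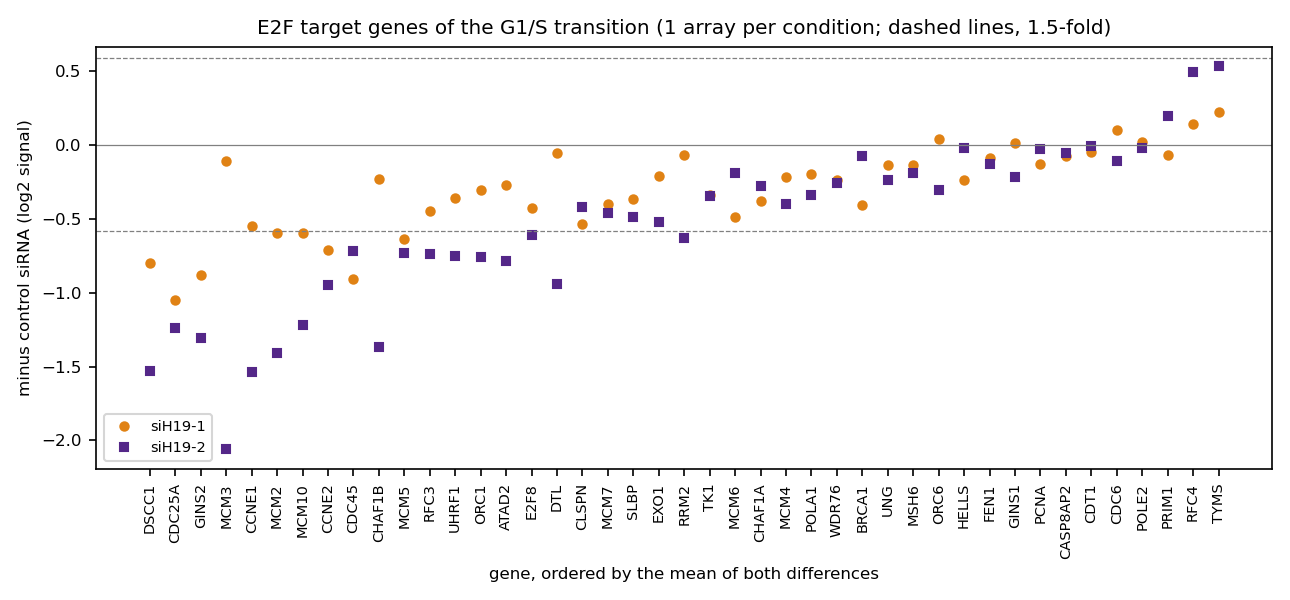
Log2 difference from the control array (vertical axis) for 43 E2F targets of G1/S, ordered by the mean of both differences, with siH19-1 as circles and siH19-2 as squares; dashed lines mark 1.5-fold. Of the 43 genes, 36 lie below 0 with both siRNAs, and the 2 medians are -0.24 and -0.42.

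The Mediator kinase module and beta-catenin core did not stand apart (medians -0.13 and -0.01, 19 genes), and CDK8 with siH19-2 was the 1 member that fell. This list, too, was fixed knowing the pathways the study followed and is not independent evidence. CTNNB1, beta-catenin, was at -0.25 and -0.16, the Mediator cyclin CCNC at -0.21 and -0.11, and the CDK8 paralog CDK19 at -0.15 and 0.15. MED13 of the same module rose with siH19-2 (0.23 and 0.74), while the transcription factor LEF1 (-0.40 and -0.33) and the kinase CSNK1A1 (0.36 and 0.23) did not reach 1.5-fold. The siH19-2 median of this list was above 0 after cyclic loess (0.04) and quantile normalization (0.11). WNT targets had medians of -0.13 and -0.15 over 22 genes (percentiles 11.5 and 16.1), or -0.07 and -0.09 after quantile normalization. Of these, CEMIP and CCND1 fell with both siRNAs, MYC was at 0.03 and -1.08, and ZNRF3, which removes WNT receptors, was at -0.30 and -0.52.

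The remaining medians moved with the scaling, and several near 0 changed sign. Hypoxia and glycolysis genes had medians of -0.06 and -0.16 over 25 genes, the first of them above 0 after cyclic loess (0.01). Among them hexokinase HK2 fell (-0.85 and -1.15) and the neuronal-type glucose transporter SLC2A3, which has a near-identical paralog and is therefore uncertain, rose (1.08 and 1.00). BNIP3L, a mitophagy receptor, rose with siH19-2 (0.43 and 0.81). Targets of p53 had medians of -0.01 and 0.04, with both signs seen across scalings; the death receptor TNFRSF10B (-0.49 and -0.54), CCNG1 (0.40 and 0.57), AEN (-0.35 and -0.55) and TIGAR (-0.26 and -0.58) did not reach 1.5-fold. With siH19-2, TNFRSF10B (-0.62), AEN (-0.63) and TIGAR (-0.66) did after median centring, where 4 genes of the list were lower against 1, and CCNG1 (0.73) did after quantile normalization. RNA interference machinery had medians of -0.21 and -0.10, the second above 0 after cyclic loess (0.02). TNRC6B (-0.37 and -1.24) and XPO5 (-0.33 and -0.62, or -0.45 after quantile normalization) fell with siH19-2, and DROSHA was at -0.46 and -0.37. TLR3, a receptor for double-stranded RNA that was also on this list, rose with siH19-2 (0.19 and 0.85).

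Reported miR-675 targets had medians of 0.10 and -0.26 over 7 genes. SMAD5 rose with siH19-1 (0.68 and 0.44), and SMAD1 (-0.14 and -0.35) and NOMO1 (-0.22 and -0.16) did not reach 1.5-fold. Ribosomal proteins had medians of -0.05 and -0.09 over 46 genes, and oxidative phosphorylation genes had medians of -0.07 and -0.07 over 52; for both lists 1 or more medians were above 0 after cyclic loess. RPS14 (-0.46 and -0.32), RPL35A (-0.23 and -0.50), NDUFB10 (-0.51 and -0.58) and CYC1 (-0.25 and -0.42) did not reach 1.5-fold (NDUFB10 did with siH19-2 after median centring, at -0.66), and COX4I1 of respiratory complex IV fell with siH19-1 (-0.79 and -0.07). Intestinal differentiation had 5 of 36 measured genes past the minimum, with medians of 0.22 and 0.19 (percentiles 99.4 and 94.3). AGR2, a disulfide isomerase of mucin-secreting cells, rose with both (0.76 and 0.59, the second 0.51 and under 1.5-fold after median centring), and MUC13 (0.55 and 0.19), DPP4 (0.16 and 0.42) and the transcription factor CDX2 (0.22 and 0.19) did not reach 1.5-fold, though MUC13 did with siH19-1 after cyclic loess (0.61). After cyclic loess (0.30 and 0.28) this list stood apart as higher with both. Epithelial adhesion genes and keratins had medians of 0.00 and -0.01 over 25 genes with members in opposite directions: CDH1 rose with both, DSG2 (-0.18 and -2.66) and EPCAM (-0.04 and -1.72) fell with siH19-2, as did the desmosomal gene PKP3 (-0.56 and -0.63).

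**Figure D3:**
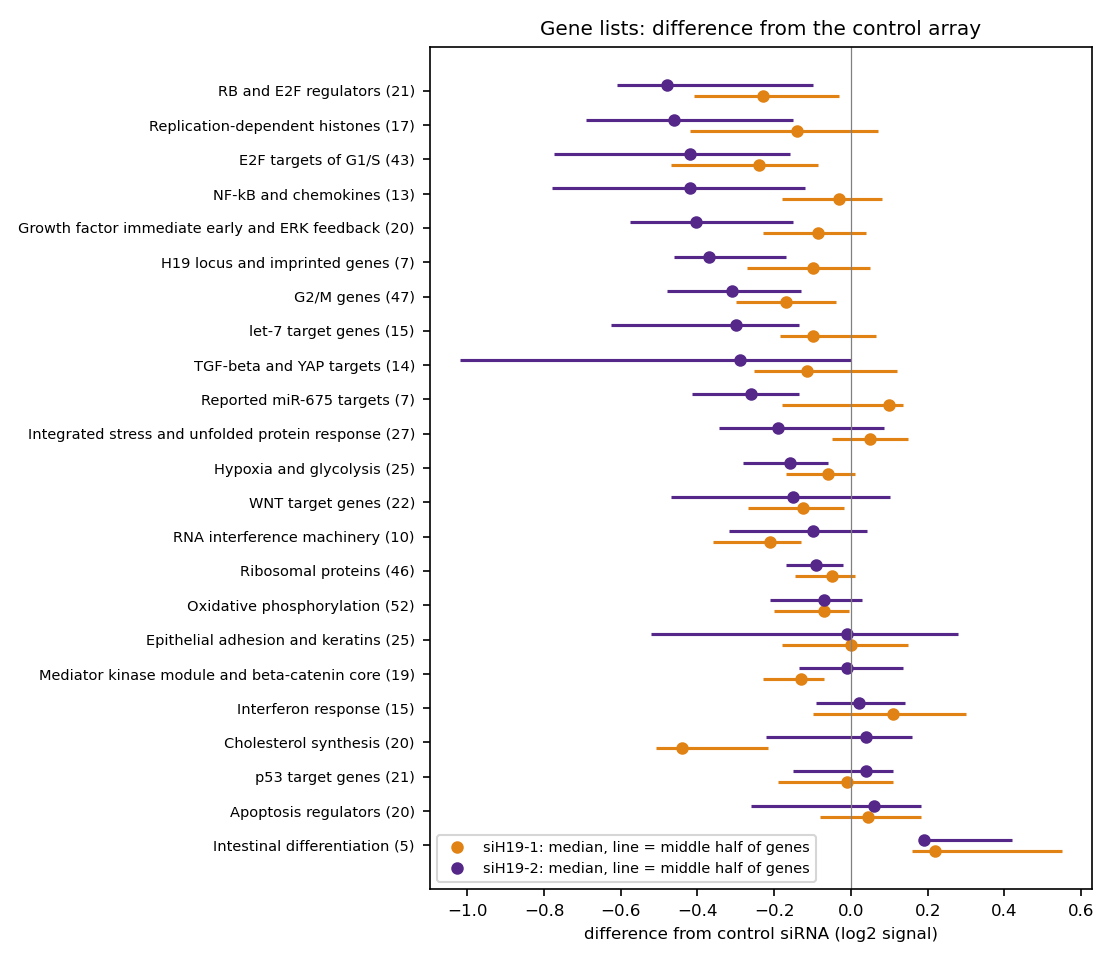
Median log2 difference from the control array (horizontal axis) for the 23 gene lists with at least 5 compared genes, with siH19-1 in orange and siH19-2 in purple; lines span the middle 50% of genes and the number of genes is in brackets. The G1/S list lies at -0.24 and -0.42, whereas cholesterol synthesis lies at -0.44 with siH19-1 and 0.04 with siH19-2.

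Set directly against each other, the siRNAs differed at least 1.5-fold in 791 genes, 549 of them higher with siH19-1 and 242 higher with siH19-2. In log2 signal, siH19-1 against siH19-2, IDH3A (12.55 against 8.55), MYBL2 (9.90 against 6.84), IGFL4 (11.73 against 8.91), AFAP1-AS1 (12.25 against 9.55) and C11orf24 (10.16 against 7.57) were the 5 genes furthest apart with siH19-1 higher. SNORA14A (5.95 against 9.12), OLR1 (12.34 against 15.23), TXNIP, an inhibitor of glucose uptake (6.70 against 9.48), SNX6 (9.78 against 12.43) and SS18 (9.61 against 11.71) were the 5 furthest apart with siH19-2 higher. Cholesterol synthesis had a median of -0.28 for siH19-1 minus siH19-2, with 0 of 10000 random lists as low. The siH19-2 median against control was 0.04, or -0.04 after median centring, 0.13 after cyclic loess and 0.16 after quantile normalization, and SCD, the stearoyl-CoA desaturase, fell with siH19-2 (-0.02 and -0.80). TGF-beta and YAP targets (0.41), ERK feedback genes (0.25), NF-kB genes (0.35), histones (0.28), imprinted genes (0.43), the stress response (0.21), let-7 targets (0.20) and RB and E2F regulators (0.24) were higher with siH19-1, with medians above the upper bound set for random lists. In the stress response the amino acid transporter SLC7A5 fell with siH19-2 (-0.14 and -1.13), and MANF was at -0.33 and -0.46. The G1/S list (0.14, percentile 95.9) and the G2/M list (0.13, percentile 96.8) lay inside the range of random lists.

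In opposite directions against control, 8 genes changed, and those other than TXNIP were named after their values were seen. CXCL5, MYD88, SNORD70, TMTC3 and UHMK1 rose with siH19-1 and fell with siH19-2, while FNBP1L, MSMO1 and TXNIP did the reverse. FNBP1L, MSMO1, MYD88 and SNORD70 no longer did after median centring, nor TMTC3 after quantile normalization. The comparison between the siRNAs holds no control array and has 1 array on each side. With the siH19-1 array as the shared reference, 106 genes lay on the same side of it in the other arrays, and with the siH19-2 array as reference 509 did, against 171 for the control array.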

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

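The results in this part are given as values; the difference between the siRNAs was not tested, because each condition has 1 array. In 8 genes the siRNAs moved signal in opposite directions by at least 1.5-fold each, which is what drew attention to them. TXNIP, whose transcription follows glucose supply, had the widest gap of the 8, at -0.90 with siH19-1 and 1.88 with siH19-2.

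A probe set with no gene name, TC04000276.hg.1, lay outside the comparisons of named genes and stood far above its control level with both siRNAs. Its log2 signal was 5.35 with control siRNA, 11.90 with siH19-1 and 13.08 with siH19-2, differences of 6.55 and 7.73 from 1 control array, in which the signal was near the minimum of 5. Among the 8034 unnamed probe sets with distinct values past the signal minimum, 2.02% were at least 1.5-fold higher with both siRNAs and 0.95% lower, against 0.69% and 1.09% of named genes.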

How the results depend on the processing

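Alternatives on protein-coding genes, haplotype probe sets, bright genes, and gene lists after median centring or quantile normalization were chosen after seeing the data. Thresholds moved counts by construction: at 2-fold, 78 genes changed with siH19-1, 302 with siH19-2, 20 with both, 1 in opposite directions and 213 between the siRNAs; at 1.3-fold these were 1309, 2508, 690, 33 and 1858. Calling on the mean of the 2 differences gave 600 genes and limma 0, with 1 residual degree of freedom. Opposite genes numbered 5 after median centring, 4 of them higher with siH19-1; the cause was not tested. All other totals stayed within 1.5 times, but the directions did not: after quantile normalization the share of higher genes went from 37.5% to 53% (siH19-1), 24.7% to 45.5% (siH19-2, 14.8% after median centring) and 38.6% to 65.6% (both). Genes higher and lower went from 283 and 862 to 470 and 562 (siH19-2), and from 66 and 105 to 105 and 55 (both, or 101 and 65 after cyclic loess). Of the 171 genes changed with both, 155 were shared with median centring, 119 with quantile normalization and 130 with cyclic loess. Scaling moved the median of all genes by less than 0.1. The H19 difference ranged from -0.17 to -0.06 with siH19-1 and from -0.59 to -0.39 with siH19-2. The agreement of the 2 siRNAs (Pearson r across genes) ranged from 0.458 to 0.511. G1/S and RB and E2F lists stood apart under all 8 list settings, and G2/M under all but the mean; histones were added with no signal minimum, and intestinal differentiation (higher) after cyclic loess or quantile normalization. Differences of named genes moved by less than the spread between the siRNA arrays in all 1056 comparisons, but for genes of the text 17 differences lost 1.5-fold under another scaling and 16 reached it. No replicate could be left out and signal over background was not used, so dim genes rest on the minimum alone.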

Other observations

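Tests on the large decreases with siH19-2 and on the size of the H19 decrease, and the added gene lists, were chosen after the result was seen; those on the G1/S genes and on other references were written before. Ribosome biogenesis genes, which process ribosomal RNA in the nucleolus, were lower with both siRNAs. The medians of 54 genes were -0.29 with siH19-1 and -0.55 with siH19-2, 0 and 0 of 10000 random lists were as low, and 46 were below control with both (45.6% of all genes were). The medians stayed below 0 after median centring, quantile normalization and cyclic loess. The helicase DDX21 (-0.81 and -1.59), the exosome subunit EXOSC5 (-0.84 and -1.37), MAK16 and WDR43 were among 9 genes that fell with both. Because the list was built after the data, with MAK16 and WDR43 among the lowest genes, had been seen, its rank among random lists is not independent evidence. For siH19-1 minus siH19-2 its median was 0.18 (percentile 99.8), so the siRNA arrays differed in this list as well. Mitochondrial ribosomal proteins had medians of -0.19 and -0.23 over 70 genes (4 and 16 of 10000 random lists as low), or -0.11 and -0.12 after quantile normalization and -0.11 and -0.15 after cyclic loess; MRPS34 (-0.69 and -2.0) and MRPL15 (-0.74 and -0.59, the second -0.47 after quantile normalization) fell with both, MRPL3 (-0.89 and -0.43) with siH19-1, and MRPL49 (0.12 and -1.60) with siH19-2. Aminoacyl-tRNA synthetases had medians of -0.15 and 0.01 over 19 genes, which change sign with the scaling. FARSA fell with both, RARS1 (0.04 and -1.99) with siH19-2, and QARS1 (-0.58 and 0.03) and NARS1 (-0.15 and -0.37) did not reach 1.5-fold with either, though QARS1 did with siH19-1 after median centring (-0.61).

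MicroRNA genes were 2.0% of compared genes but 13.6% of those higher with both siRNAs, 9 genes, of which 5 were annotated to the MIR548 family, whose members have similar sequences. The 197 microRNA genes lay higher as a kind, with medians of 0.13 and 0.30 against -0.07 and -0.09 for protein-coding genes, and 2 fell with both. FOXM1 (-0.62 and -1.16) and MYB (-0.70 and -1.20), transcription factors of proliferating cells named after their values were seen, fell with both, FOXM1 no longer after quantile normalization (-0.52 with siH19-1).

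The lower G1/S genes with both siRNAs may reflect the control array, a scaling that misses a shift with signal, or the siRNAs against H19. After cyclic loess the list's medians went from -0.24 and -0.42 to -0.164 and -0.297, at percentile 0.0 with both siRNAs. The random lists were matched on signal with or without loess, so a shift with signal would move them alike. The rank among matched lists argues against such a shift as the whole cause, and loess adds little to it. Between the siRNA arrays, which hold no control, the list ranked at percentile 95.91, inside the range of random lists, as it would if the control array alone stood apart. It would also lie there if both siRNAs lowered these genes alike, so the control array, or an off-target effect of the control siRNA, and loss of H19 cannot be told apart with 1 control. With each array in turn as the reference the 3 arrays allow 3 splits, too few for a share under 0.05: the real one gave 171 genes and the highest other 509, 2 of the 3 gave 171 or more, and the larger value points to a structure of the samples, with the siH19-2 array furthest from the rest.

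The small difference of the H19 probe set could come from a probe set at the floor, or from an array unable to show a decrease at that signal. Its mean signal lay at percentile 87.4 of all probe sets, which argues against the floor. Of 1665 genes within 0.5 log2 units of its signal, 42 were at least 2-fold lower with siH19-2. This argues against an array unable to show any such decrease at that signal. It cannot tell whether the H19 probe set itself responds to loss of H19, because the count rests on other probe sets. Weak depletion at the time of harvest, and cross-signal at this probe set, were not tested and remain open.

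Large decreases with siH19-2 could follow from loss of H19 or from other targets of this siRNA. Of the 25 genes at least 4-fold lower with siH19-2, 5 were at least 1.5-fold lower with siH19-1, where 2.6% of all compared genes were. Both differences share the control array, which by itself raises such an overlap. The H19 probe set was lower by 0.37 with siH19-2 than with siH19-1, where the SD of that difference over the compared genes was 0.364. Whether depletion differed between the siRNAs is therefore not known. The absence of the other decreases with siH19-1 does not exclude loss of H19, and the 2 causes cannot be told apart here. Matches between the siRNA sequences and the genes that fell were not analysed.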
